A study of Mus musculus with 16 samples.

How the data were processed

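Liver RNA from mice with hepatocyte deletion of Arid1b (BKO) or of Arid1a and Arid1b (DKO) and from Cre-negative controls was extracted with TRIzol and prepared with a NuGEN Ovation kit, per the labels' protocols. The deposited values are counts per gene, 1 table per experiment, whole and not normalized. Trim Galore 0.4.1, HISAT2 2.1.0 and featureCounts 1.6.2 are named per the submitters' processing notes, which list the builds GRCm38, mm10 and GRCh38 without saying where each was used. The strand setting, the gene annotation and the treatment of reads shared between genes are not given in the sources used here. Of the 175 genes named, all of which matched GENCODE M21 by symbol, 73 overlap another annotated gene there and 58 have a gene on the opposite strand, so part of their counts may belong to the partner. Genes given with values that overlap another gene are Arid1a, Arid1b, H19, Igf2, Sult3a1, Hamp2, Cyp2b13, Dct, Smarca2, Igf2bp3, Scd2, Prom1, Bicc1, Elf3, Tspan8, Col4a1, Fbn1, Mmp12, Cx3cr1, Ptprb, Top2a, Plk1, Prc1, Mki67, Nr1i3, Notum, Sds, Slco1a1, Mlxipl, Hadha, Pex11a, Prodh, Gnmt, Pkm, Igf1, Gbp2, Cxcl10, Cd74, Tgfb2, Tgfb3, Jun, Usp2, Cyp2a4, Tcf24, Chaf1a, Pole, Cyp2u1, Col5a3, Rhbg, Cyp2f2 and Elovl3. Coordinates are from GENCODE M21 on GRCm38.

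Samples were grouped by the genotype in the labels, and libraries were named by the animal tags in the labels. Each table held 24421 rows, and 0 columns were left without a sample. Among the BKO names, 27 had turned into dates, and these rows stayed in the BKO test, were named nowhere and were left out of the joint fit, which used 24394 genes. No gene name started with mt-, so the list of mitochondrially encoded genes was not analysed here. Total counts were 8699417 to 11031443 in the DKO experiment and 21151726 to 40551934 in the BKO experiment. That each library came from a separate animal rests on the tags, and 2 BKO controls were labelled F5 and F5-2. Their counts differed beyond sampling noise, with a chi-square of 70.4 per degree of freedom and a dispersion of 0.0573 that lay within the range of the other control pairs, 0.0279 to 0.0601, so they were kept as 2 libraries. Whether they came from 1 animal is not given in the sources used here, so a fit with both summed was an alternative. The closest pair was DKO-7068 and DKO-7070, with a chi-square of 7.35 per degree of freedom. Its dispersion was 0.0150, against 0.0473 to 0.0705 for the other DKO pairs. Their tags differ and they were kept as 2 libraries, with a summed fit added after the data had been seen.

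Counts were tested in R 4.3.3 with edgeR 4.0.16, by robust quasi-likelihood fits after filterByExpr and TMM scaling, within each experiment and, for the difference of the knockout effects, over all 16 libraries. DKO and BKO libraries were not compared directly, since they were in separate tables of different depth. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. Folds are ratios of mean CPM, and where a whole group had no count they were taken against 3 counts over that group. Of 46 gene lists fixed before the data were examined, 45 were for testing, and those with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over lists. Estimated correlations and fry were alternatives, and fry asks whether the genes of a list move one way on balance without a comparison to other genes. The median, the mean and the test differed in sign for 2 DKO lists, 8 BKO lists and 2 lists of the difference, 0 of them called. In DKO and BKO, setting genes with an empty group to their bound left each list median as given. Medians of the difference were not recomputed this way, and where members had groups at or near 0 counts they depend on the prior count. Named genes followed a rule fixed before the data were examined: the targeted genes, the 10 higher and 10 lower genes with the largest change among those called, separated between groups and at a mean log2 CPM of at least 1, up to 4 members by p of each called list and up to 2 of other lists, and 5 each way for the difference. Clone, model and pseudogene names were passed over.

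The steps were tested on simulated counts with 200 changed genes. At 1.5, 2 and 4-fold, edgeR recovered 10.4%, 62.7% and 95.5% of them for DKO (12848 genes), 22.4%, 64.2% and 87.9% for BKO (14061 genes) and 4.48%, 34.3% and 83.3% for the difference (14050 genes). False calls made up 5.08%, 6.45% and 5.81% of its calls, and 17.5%, 15.3% and 20.5% of those of DESeq2 in the same simulations. Alternatives were DESeq2 1.42.0 size factors, total counts only, removal of the 20 most abundant genes, no filter or at least 1 CPM in 4 libraries, the DESeq2 Wald test, limma 3.58.1 with voom, a 2-fold minimum, each library left out in turn, all 16 libraries in one fit, the tag series as a batch in the DKO experiment, and both F5 libraries summed. The count filter was rerun with each library left out, so the members behind a list median can differ from those of the main fit. The term for sex was not run because all libraries were female.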

Results

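Messenger RNA of whole mouse liver was sequenced in 16 libraries that formed 4 groups of 4. ARID1A and ARID1B are alternative subunits of the BAF complex, an ATP-dependent chromatin remodeller, and Alb-Cre is a recombinase transgene active in hepatocytes. The DKO group carried floxed alleles of both Arid1a and Arid1b together with Alb-Cre, and its controls carried the same floxed alleles without Cre. The BKO group carried floxed Arid1b and Alb-Cre, with Cre-negative floxed controls. Total counts ran from 8699417 to 11031443 per library in the DKO experiment and from 21151726 to 40551934 in the BKO experiment. All 16 libraries came from females by their counts, with 17511 to 86791 counts of Xist and at most 1 count over 4 Y-linked genes. Levels are normalized CPM, mean ± SD over n = 4 libraries per group, knockout against its own controls.

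The targeted genes were read first in each library. Arid1b (chromosome 17, 4994332 to 5347656 on GRCm38) was lower in BKO livers, at 44.3 ± 3.98 against 84.8 ± 2.01 CPM (log2 fold change -0.94, SE 0.09, edgeR adjusted p = 0.00154, n = 4 per group). Its levels were 41.7 in F1, 46.8 in F3, 40.1 in F4, 48.4 in F6, against 85.5 in F2, 86.4 in F5, 85.5 in F5-2, 81.9 in F7 in the controls. In DKO livers Arid1b was at 60.03 ± 13.7 against 89.3 ± 9.17 CPM (log2 fold change -0.57, SE 0.16, edgeR adjusted p = 0.0167). It was at 55.4 in DKO-7068, 61.4 in DKO-7070, 78.0 in DKO-7112, 45.4 in DKO-7137, against 80.7 in WT-7067, 82.0 in WT-7069, 97.1 in WT-7114, 97.3 in WT-7139 in the controls. Arid1a (chromosome 4, 133679008 to 133756769) did not pass the test in DKO livers, at 108 ± 6.08 against 124 ± 10.2 CPM (log2 fold change -0.20, SE 0.10, edgeR adjusted p = 0.149). It was at 110.3 in DKO-7068, 99.6 in DKO-7070, 106 in DKO-7112, 114 in DKO-7137, against 128 in WT-7067, 112 in WT-7069, 136 in WT-7114, 118 in WT-7139 in the controls. Arid1a did not pass in BKO livers either, at 128 ± 13.2 against 123 ± 8.38 CPM (log2 fold change 0.06, SE 0.10, edgeR adjusted p = 0.883). It was at 129 in F1, 137 in F3, 108 in F4, 136 in F6, against 119 in F2, 127 in F5, 132 in F5-2, 113 in F7 in the controls. The counts cover whole genes and whole liver, and the floxed exons are not given in the sources used here, so these levels do not check the deletions exon by exon. The Arid1b call in DKO livers ended when library DKO-7068 was left out (-0.54, edgeR adjusted p = 0.0515) and with scaling by total counts only (-0.39, adjusted p = 0.091).

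**Figure D1:**
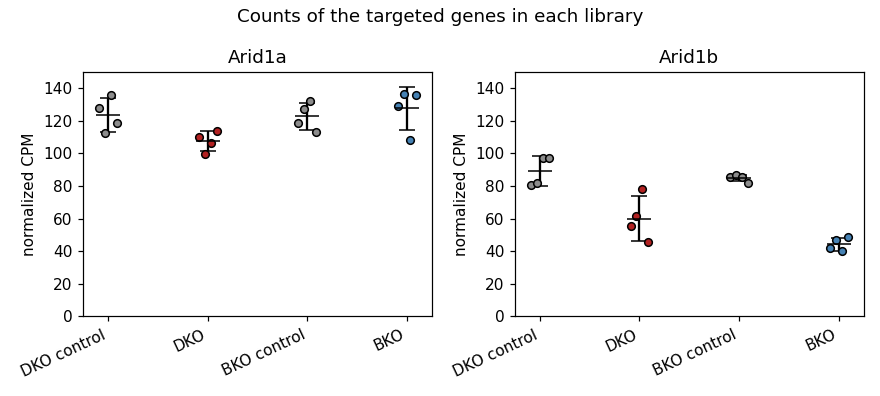
Normalized CPM of Arid1a and Arid1b (vertical axes) in each library (points) of the DKO, BKO and control groups, with the mean and SD of each group as horizontal and vertical bars. The 4 BKO libraries sat between 40.1 and 48.4 CPM of Arid1b, below all of their controls, while Arid1a did not pass the test in either knockout.

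The first comparison set livers with loss of ARID1A and ARID1B against their controls. No group lost ARID1A alone, so an effect of the combined loss cannot be told apart from that of ARID1A loss. Cre was present in all DKO libraries and in none of their controls, so its own effect cannot be told apart either. H19, an imprinted noncoding RNA of fetal liver (chromosome 7, 142575529 to 142578143), stood at 2717 ± 1397 against 2.44 ± 1.961 CPM (log2 fold change 10.14, SE 0.82, edgeR adjusted p = 6.22e-05, n = 4 per group). Its imprinted neighbour Igf2, which encodes a fetal growth factor (chromosome 7, 142650766 to 142666816), stood at 579 ± 379.9 against 0.823 ± 0.305 CPM (log2 fold change 9.47, SE 1.16, edgeR adjusted p = 0.000616). Of 12848 genes tested, 2467 were higher and 2137 lower in DKO livers, 1433 and 703 of them by at least 2-fold. The secreted Wnt inhibitor gene Wif1 had no count in the controls and 30.9 ± 9.83 CPM in DKO livers, at least 373-fold higher. Tff3, a secreted mucosal peptide gene, reached 202 ± 99.5 against 0.167 ± 0.114 CPM, and the brush border cadherin gene Cdhr2 129.9 ± 28.1 against 0.266 ± 0.308 CPM. The keratin gene Krt20 was at 27.4 ± 15.7 against 0.0560 ± 0.0647 CPM and Wfdc3 at 12.5 ± 8.68 against 0.0280 ± 0.0561 CPM, with control levels that rested on 1 or 2 counts. Without WT-7139 the control mean of H19 was 1.48 CPM, and without WT-7114 those of Cdhr2, Krt20 and Wfdc3 were 0.168, 0.0373 and 0 CPM. Sprr1a was at least 68.9-fold higher, Rbm24, which encodes an RNA-binding protein, at least 43.0-fold and Serpina1f at least 42.6-fold, each without a count in the controls. Floors were 3 counts over the group and cover counting error only.

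Of 18 tested fetal and oncofetal liver genes, 13 rose, 1 fell and 4 did not pass (13 and 1 adjusted over the list alone). Fetal and oncofetal liver genes had a median log2 fold change of 2.31 (camera adjusted p = 7.19e-08, and adjusted p = 0.0175 with an estimated correlation). Igf2bp3, an RNA-binding protein gene of fetal tissues, rose 5.98-fold (31.0 ± 3.50 against 5.19 ± 0.540 CPM), and the fatty acid desaturase gene Scd2 rose 34.8-fold (590.1 ± 309 against 16.97 ± 4.33 CPM). Of 11 tested bile duct markers, 6 rose, 0 fell and 5 did not pass (6 and 0 adjusted over the list alone). Bile duct markers had a median log2 fold change of 0.52 (camera adjusted p = 0.00302, and adjusted p = 0.173 with an estimated correlation). Prom1, a membrane protein gene of biliary and progenitor cells, was 12.8-fold higher, Bicc1 4.88-fold, the epithelial transcription factor gene Elf3 18.4-fold and Tspan8 7.20-fold. Without DKO-7112, Elf3 was 10.3-fold and Tspan8 4.65-fold higher. The median of bile duct markers was 1.31 without DKO-7112, 1.89 without DKO-7137, and 1.34 to 1.66 without any 1 of the controls. In these refits 13062 to 13177 genes passed the rerun count filter, against 12848 with all libraries. The medians may thus cover other members than the 11 behind 0.52, and do not by themselves show dependence on a single library.

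Of 34 tested stellate cell and matrix genes, 28 rose, 1 fell and 5 did not pass (28 and 1 adjusted over the list alone). Stellate cell and matrix genes had a median log2 fold change of 2.03 (camera adjusted p = 9.89e-31, and adjusted p = 0.0419 with an estimated correlation). Col4a1, a basement membrane collagen gene, stood at 279 ± 16.9 against 54.7 ± 6.57 CPM (log2 fold change 2.35, SE 0.12, edgeR adjusted p = 2.31e-06). Pdgfrb, a receptor gene of stellate cells, rose 3.82-fold, the intermediate filament gene Vim 4.32-fold and the fibrillin gene Fbn1 6.88-fold. Of 16 tested recruited macrophage markers, 15 rose, 0 fell and 1 did not pass (16 and 0 adjusted over the list alone). Recruited macrophage markers had a median log2 fold change of 2.90 (camera adjusted p = 3.22e-19, and adjusted p = 0.0303 with an estimated correlation). The macrophage elastase gene Mmp12 was at 21.1 ± 6.37 against 0.215 ± 0.113 CPM, the chemokine receptor gene Cx3cr1 at 18.6 ± 3.37 against 0.695 ± 0.433 CPM and the integrin gene Itgax at 15.6 ± 3.56 against 1.68 ± 0.558 CPM. Of 15 tested Kupffer cell markers, 6 rose, 2 fell and 7 did not pass (6 and 3 adjusted over the list alone). Kupffer cell markers did not pass as a list (camera adjusted p = 0.345). The complement genes C1qc and C1qb, made by macrophages, rose 1.962-fold and 2.09-fold. Of 22 tested endothelial markers, 2 rose, 8 fell and 12 did not pass (4 and 9 adjusted over the list alone). Endothelial markers did not pass as a list (camera adjusted p = 0.119). Bmp2 was 1.77-fold and the phosphatase gene Ptprb 1.46-fold lower, and the Ptprb call ended with total-count scaling. Albumin (Alb), the main hepatocyte transcript, took 3.76% to 6.38% of counts in DKO libraries and 8.62% to 9.94% in their controls.

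Of 23 tested G2 and M phase genes, 23 rose, 0 fell and 0 did not pass (23 and 0 adjusted over the list alone). G2 and M phase genes had a median log2 fold change of 2.66 (camera adjusted p = 2e-22, and adjusted p = 0.0849 with an estimated correlation). The topoisomerase gene Top2a stood at 31.3 ± 7.07 against 4.13 ± 0.313 CPM and the proliferation marker Mki67 at 61.0 ± 13.8 against 10.1 ± 2.01 CPM. The mitotic kinase gene Plk1 was 15.3-fold and Prc1 7.44-fold higher. Of 24 tested S phase genes, 15 rose, 1 fell and 8 did not pass (16 and 1 adjusted over the list alone). S phase genes had a median log2 fold change of 1.09 (camera adjusted p = 0.000693, and adjusted p = 0.479 with an estimated correlation). They included Uhrf1, which maintains DNA methylation (8.37-fold higher), Cdc6 (6.92-fold) and the cyclin gene Ccne1 (5.74-fold). Of 21 tested target genes of p53, 12 rose, 1 fell and 8 did not pass (12 and 3 adjusted over the list alone). Target genes of p53 had a median log2 fold change of 0.73 (camera adjusted p = 0.0038, and adjusted p = 0.208 with an estimated correlation). Phlda3 rose 9.32-fold and Ccng1 2.07-fold. Of 24 tested NRF2 target genes, 12 rose, 2 fell and 10 did not pass (15 and 2 adjusted over the list alone). NRF2 target genes had a median log2 fold change of 0.96 (camera adjusted p = 4.37e-05, and adjusted p = 0.188 with an estimated correlation). The glutathione transferase genes Gstm3 and Gsta4 rose 21.4-fold and 3.53-fold. Recruited macrophage markers, with a median of 2.90, were higher beside these groups.

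Of 28 tested acute phase genes, 16 rose, 1 fell and 11 did not pass (21 and 1 adjusted over the list alone). Acute phase genes had a median log2 fold change of 1.30 (camera adjusted p = 0.000695, and adjusted p = 0.503 with an estimated correlation). The median was 0.81 without DKO-7112. Hemopexin (Hpx), which binds free heme, reached 10875 ± 3153 against 2145 ± 317 CPM, and the protease inhibitor gene Serpina3n 3488 ± 1693 against 467 ± 60.5 CPM. Of 29 tested interferon stimulated genes, 11 rose, 0 fell and 18 did not pass (11 and 0 adjusted over the list alone). Interferon stimulated genes had a median log2 fold change of 0.62 (camera adjusted p = 5.91e-05, and adjusted p = 0.431 with an estimated correlation). The GTPase gene Gbp2 rose 8.68-fold and the chemokine gene Cxcl10 5.25-fold. Of 14 tested antigen presentation genes, 9 rose, 2 fell and 3 did not pass (11 and 2 adjusted over the list alone). Antigen presentation genes had a median log2 fold change of 1.44 (camera adjusted p = 5.7e-05, and adjusted p = 0.258 with an estimated correlation). Cd74, the MHC class II invariant chain gene, was at 207 ± 49.4 against 64.3 ± 17.4 CPM. Library DKO-7070 stood apart for Cd74 (280.0 CPM) and the MHC class II gene H2-Aa (99.6 CPM). Of 18 tested YAP and TEAD targets, 8 rose, 0 fell and 10 did not pass (8 and 0 adjusted over the list alone). YAP and TEAD targets had a median log2 fold change of 0.47 (camera adjusted p = 0.0013, and adjusted p = 0.326 with an estimated correlation). Myof rose 4.39-fold and Ajuba 3.69-fold. Of 20 tested TGF-beta pathway genes, 9 rose, 1 fell and 10 did not pass (10 and 1 adjusted over the list alone). TGF-beta pathway genes had a median log2 fold change of 0.65 (camera adjusted p = 0.00206, and adjusted p = 0.208 with an estimated correlation). The ligand gene Tgfb2 rose 6.73-fold and the receptor gene Tgfbr2 2.15-fold. Recruited macrophage markers (median 2.90, 15 of 16 higher) moved with these groups.

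Of 23 tested pericentral hepatocyte genes, 1 rose, 18 fell and 4 did not pass (1 and 18 adjusted over the list alone). Pericentral hepatocyte genes had a median log2 fold change of -2.20 (camera adjusted p = 2e-19, and adjusted p = 0.0175 with an estimated correlation). Cyp2e1, which oxidises ethanol, stood at 527 ± 48.3 against 5041 ± 955 CPM (log2 fold change -3.26, SE 0.19, edgeR adjusted p = 3.14e-06), and Notum, a secreted Wnt deacylase gene, at 5.91 ± 1.17 against 49.4 ± 9.79 CPM. Of 19 tested periportal genes, 3 rose, 4 fell and 12 did not pass (3 and 4 adjusted over the list alone). Periportal genes did not pass as a list (camera adjusted p = 0.387). Etnppl was 2.66-fold lower and the serine dehydratase gene Sds 2.33-fold higher. Of 35 tested phase 1 enzyme genes, 4 rose, 23 fell and 8 did not pass (5 and 25 adjusted over the list alone). Phase 1 enzyme genes had a median log2 fold change of -1.24 (camera adjusted p = 1.89e-16, and adjusted p = 0.0303 with an estimated correlation). The carboxylesterase gene Ces1f was at 0.504 ± 0.251 against 239 ± 20.5 CPM (475-fold lower) and Cyp2c50 at 67.9 ± 4.21 against 667 ± 55.1 CPM. Of 26 tested phase 2 conjugation genes, 3 rose, 13 fell and 10 did not pass (3 and 15 adjusted over the list alone). Phase 2 conjugation genes had a median log2 fold change of -0.66 (camera adjusted p = 2.11e-07, and adjusted p = 0.0419 with an estimated correlation). The glucuronosyltransferase genes Ugt2b1 and Ugt3a2 fell 8.13-fold and 12.6-fold. The sulfotransferase gene Sult3a1 had no count in DKO livers and 43.1 ± 14.2 CPM in the controls, at least 606-fold lower. Hamp2, a paralog of the iron hormone gene hepcidin, fell 384-fold, the major urinary protein gene Mup6 209-fold, Serpina1e 164-fold, Cyp2b13 168-fold and Cyp3a41a 154-fold. Dct was at 0.0271 ± 0.0543 against 5.66 ± 2.47 CPM, Mup5 at 0.0271 ± 0.0543 against 4.18 ± 2.25 CPM and Cyp4a12a at 0.0477 ± 0.0561 against 5.81 ± 6.82 CPM, with DKO levels that rested on 1 or 2 counts. Without DKO-7112 the DKO means of Dct, Mup5, Cyp4a12a and Mup6 were 0, 0, 0.0274 and 0.0345 CPM. Without WT-7114 the control mean of Cyp4a12a was 2.44 CPM. Hamp2 was 613-fold lower without DKO-7137, Cyp3a41a 268-fold without DKO-7068 and Serpina1e 100.5-fold without WT-7139. The albumin share, 3.76% to 6.38% in DKO libraries against 8.62% to 9.94%, was lower beside these groups.

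**Figure D2:**
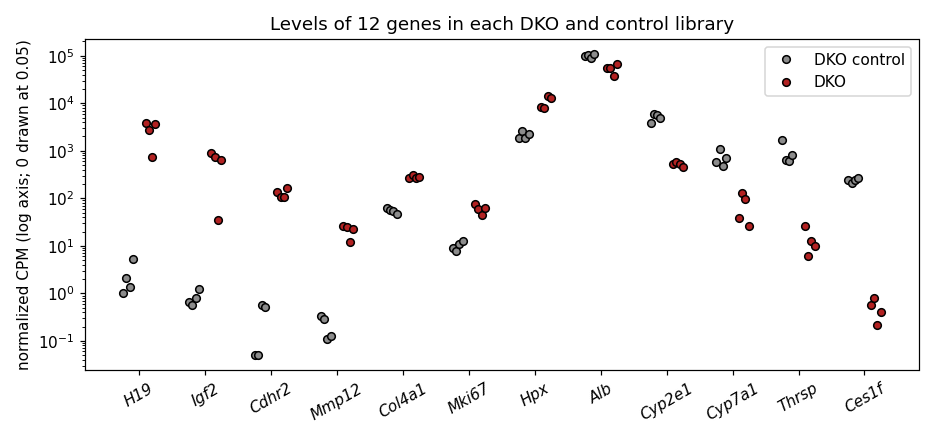
Normalized CPM on a log axis, with 0 drawn at 0.05, of 12 genes in each of the 4 DKO libraries (red) and 4 control libraries (grey). H19, Igf2, Cdhr2, Mmp12, Col4a1, Mki67 and Hpx lay above the controls in every DKO library, and Alb, Cyp2e1, Cyp7a1, Thrsp and Ces1f lay below.

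Of 15 tested bile acid synthesis genes, 0 rose, 10 fell and 5 did not pass (2 and 11 adjusted over the list alone). Bile acid synthesis genes had a median log2 fold change of -0.85 (camera adjusted p = 0.000119, and adjusted p = 0.137 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of the pathway, stood at 72.4 ± 48.2 against 714 ± 271 CPM (log2 fold change -3.30, SE 0.55, edgeR adjusted p = 0.00218). Of 23 tested fatty acid synthesis genes, 0 rose, 16 fell and 7 did not pass (0 and 18 adjusted over the list alone). Fatty acid synthesis genes had a median log2 fold change of -1.63 (camera adjusted p = 5.98e-08, and adjusted p = 0.258 with an estimated correlation). Thrsp, a lipogenic factor gene, fell 67.6-fold, the acyltransferase gene Dgat2 3.69-fold and Mlxipl, which encodes the carbohydrate response factor ChREBP, 2.91-fold. Of 30 tested fatty acid oxidation genes, 2 rose, 15 fell and 13 did not pass (2 and 16 adjusted over the list alone). Fatty acid oxidation genes had a median log2 fold change of -0.58 (camera adjusted p = 0.00185, and adjusted p = 0.517 with an estimated correlation). Hadha, a mitochondrial beta-oxidation enzyme gene, fell 1.70-fold and the peroxisomal membrane protein gene Pex11a 2.51-fold. Of 32 tested urea cycle and amino acid genes, 1 rose, 13 fell and 18 did not pass (2 and 14 adjusted over the list alone). Urea cycle and amino acid genes had a median log2 fold change of -0.40 (camera adjusted p = 0.00278, and adjusted p = 0.503 with an estimated correlation). The proline dehydrogenase gene Prodh fell 8.10-fold and Gnmt 3.94-fold. Of 15 tested gluconeogenesis and glycogen genes, 1 rose, 8 fell and 6 did not pass (2 and 9 adjusted over the list alone). Gluconeogenesis and glycogen genes had a median log2 fold change of -0.87 (camera adjusted p = 0.00143, and adjusted p = 0.208 with an estimated correlation). The glycogen synthase gene Gys2 fell 4.40-fold. Of 32 tested nuclear oxidative phosphorylation genes, 0 rose, 27 fell and 5 did not pass (0 and 28 adjusted over the list alone). Nuclear oxidative phosphorylation genes had a median log2 fold change of -0.55 (camera adjusted p = 7.38e-08, and adjusted p = 0.258 with an estimated correlation). Ndufv1 fell 1.80-fold and Sdhd 1.67-fold. Of 27 tested plasma protein genes, 2 rose, 13 fell and 12 did not pass (2 and 13 adjusted over the list alone). Plasma protein genes had a median log2 fold change of -0.45 (camera adjusted p = 0.000695, and adjusted p = 0.258 with an estimated correlation). The apolipoprotein gene Apoc3 fell 4.39-fold and the growth factor gene Igf1 2.29-fold. Of 32 tested complement and coagulation genes, 6 rose, 10 fell and 16 did not pass (6 and 10 adjusted over the list alone). Complement and coagulation genes had a median log2 fold change of -0.13 (camera adjusted p = 0.0427, and adjusted p = 0.697 with an estimated correlation). Their median changed sign with total-count scaling, and their call ended without DKO-7068, DKO-7070, WT-7069 or WT-7139 (camera adjusted p = 0.112, 0.103, 0.0505 and 0.0939). The median was -0.22 without DKO-7112. The lectin gene Mbl2 fell 5.22-fold. Beside these groups the albumin share was lower (3.76% to 6.38% in DKO libraries against 8.62% to 9.94%) and recruited macrophage markers were higher (median 2.90).

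Of the 41 lists tested, camera called 14 higher and 14 lower. With an estimated correlation 6 of these calls held: fetal, matrix, macrophage, pericentral, phase 1 and phase 2 genes. With fry 25 held, and those of acute phase, fatty acid oxidation and complement genes ended (fry adjusted p = 0.0510, 0.0562 and 0.123). Fry also called liver transcription factor, BAF subunit, bile transport and B and plasma cell genes (fry adjusted p = 0.00238, 0.00431, 0.00287 and 0.00238), which camera did not. Of the 35 ways to divide the 8 libraries into 4 and 4, 3 gave at least 28 camera calls, the real one included, so this count alone does not set DKO livers apart. Scaling by total counts only gave 3266 higher and 1269 lower genes, and moved the median of all genes from 0.02 to 0.20 on the log2 scale. Of the 175 genes picked by the naming rule, 73 overlap another annotated gene, among them Arid1a, Arid1b, H19, Igf2, Igf2bp3, Col4a1, Mmp12, Cx3cr1, Top2a, Mki67, Plk1, Notum, Sult3a1, Smarca2, Tcf24, Elovl3 and Chaf1a. The P450, Ces, Sult, Ugt, Gst, Mup, Serpina1 and Hamp genes have close paralogs. Their values are uncertain, as the strand setting and the treatment of shared reads are not given in the sources used here.

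**Figure D3:**
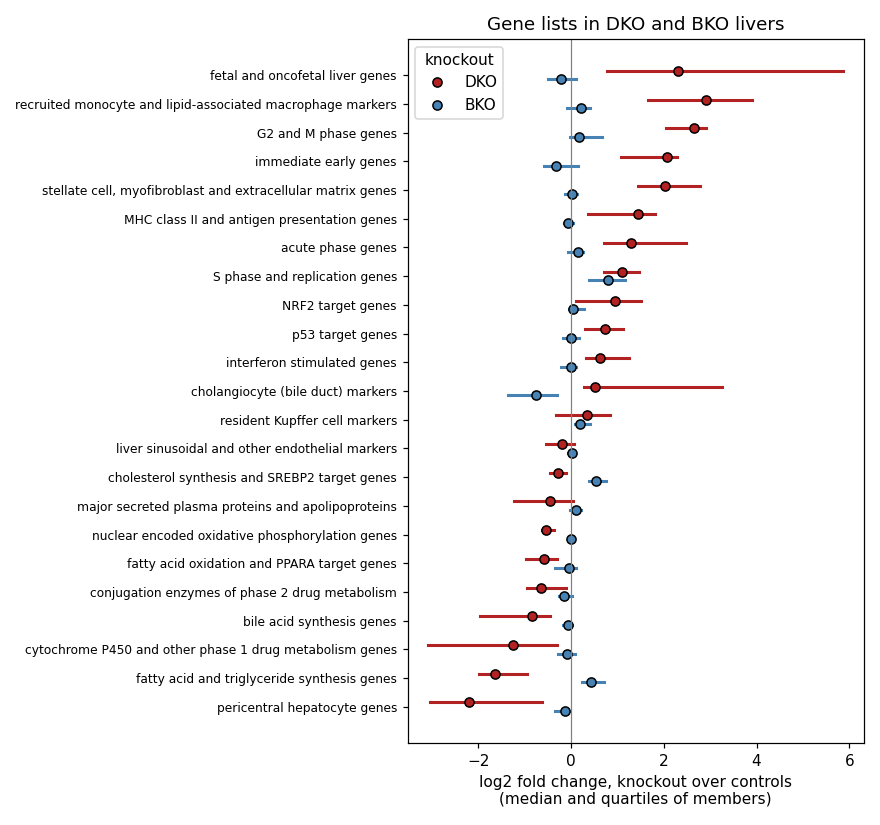
Median log2 fold change (points) and quartiles (bars) of the tested members of 23 gene lists, DKO over its controls in red and BKO over its controls in blue. In DKO livers the medians shown included -2.20 for pericentral genes and 2.90 for macrophage markers.

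The second comparison set livers with loss of ARID1B alone against their controls, again with Cre in the knockouts only. The drug-metabolising P450 gene Cyp3a11 (chromosome 5, 145854426 to 145879964) fell 8.22-fold in BKO livers, at 101 ± 35.8 against 834 ± 101 CPM (log2 fold change -3.04, SE 0.24, edgeR adjusted p = 0.00154, n = 4 per group). Uhrf1 rose to 3.71 ± 1.36 against 0.856 ± 0.380 CPM (log2 fold change 2.11, SE 0.36, edgeR adjusted p = 0.0257), and the replicative helicase genes Mcm2 and Mcm4 were 2.86-fold and 2.20-fold higher. In all, 26 genes were higher and 56 lower of 14061 tested, 14 and 24 of them by at least 2-fold.

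The transcription factor gene Tcf24 rose to 15.3 ± 2.37 against 4.90 ± 0.856 CPM (log2 fold change 1.65, SE 0.16, edgeR adjusted p = 0.00154). Mms22l, a replication repair factor gene, rose 3.02-fold, the chromatin assembly gene Chaf1a 2.50-fold and the DNA polymerase epsilon gene Pole 2.31-fold. Dntt, Nodal and Dpy19l3 rose 2.92-fold, 2.86-fold and 2.32-fold. The terminal complement gene C9 fell to 25.6 ± 5.30 against 134 ± 34.4 CPM (log2 fold change -2.39, SE 0.23, edgeR adjusted p = 0.00392) and Ugt3a1 to 4.83 ± 1.79 against 24.4 ± 6.51 CPM. The NADPH oxidase gene Nox4 fell 12.7-fold, and was 8.30-fold lower without control F7 and 19.4-fold without F6. Ces2c fell 4.88-fold, Cyp2u1 4.23-fold, the collagen gene Col5a3 4.12-fold and Dsg1c 3.40-fold. The glutamate transporter gene Slc17a8 fell 3.20-fold and Rarres1 2.83-fold. Elovl3, a fatty acid elongase gene, had no count in BKO livers and 0.744 ± 0.267 CPM in the controls, at least 31.0-fold lower.

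Of the 42 lists tested in BKO livers, camera called 5 higher and 3 lower. Of 24 tested S phase genes, 4 rose, 0 fell and 20 did not pass (11 and 1 adjusted over the list alone). S phase genes had a median log2 fold change of 0.79 (camera adjusted p = 2.12e-14, and adjusted p = 0.499 with an estimated correlation). Of 25 tested cholesterol synthesis genes, 0 rose, 0 fell and 25 did not pass (0 and 0 adjusted over the list alone). Cholesterol synthesis genes had a median log2 fold change of 0.53 (camera adjusted p = 2.04e-12, and adjusted p = 0.616 with an estimated correlation). Of 23 tested fatty acid synthesis genes, 0 rose, 0 fell and 23 did not pass (0 and 0 adjusted over the list alone). Fatty acid synthesis genes had a median log2 fold change of 0.42 (camera adjusted p = 0.000133, and adjusted p = 0.659 with an estimated correlation). Of 21 tested ER stress genes, 1 rose, 0 fell and 20 did not pass (7 and 1 adjusted over the list alone). ER stress genes had a median log2 fold change of 0.50 (camera adjusted p = 0.00178, and adjusted p = 0.536 with an estimated correlation). The chaperone gene Hspa5 rose 1.66-fold. Of 21 tested G2 and M phase genes, 0 rose, 0 fell and 21 did not pass (0 and 0 adjusted over the list alone). G2 and M phase genes had a median log2 fold change of 0.18 (camera adjusted p = 0.00867, and adjusted p = 0.659 with an estimated correlation). Of 19 tested bile duct markers, 0 rose, 0 fell and 19 did not pass (0 and 2 adjusted over the list alone). Bile duct markers had a median log2 fold change of -0.76 (camera adjusted p = 0.000708, and adjusted p = 0.536 with an estimated correlation). Of 35 tested phase 1 enzyme genes, 0 rose, 2 fell and 33 did not pass (0 and 4 adjusted over the list alone). Phase 1 enzyme genes had a median log2 fold change of -0.09 (camera adjusted p = 0.00112, and adjusted p = 0.499 with an estimated correlation). The members that fell were Cyp3a11 and Cyp2f2 (1.94-fold). Of 23 tested pericentral hepatocyte genes, 0 rose, 1 fell and 22 did not pass (2 and 5 adjusted over the list alone). Pericentral hepatocyte genes had a median log2 fold change of -0.13 (camera adjusted p = 0.0155, and adjusted p = 0.536 with an estimated correlation). The ammonium transporter gene Rhbg fell 2.29-fold. Macrophage markers, with a median of 0.22 (camera adjusted p = 0.969), and matrix genes, with 0.03 (camera adjusted p = 0.969), did not pass. Of the 8 camera calls, 0 held with an estimated correlation or with fry. Over all 42 lists, 2 and 6 had an unadjusted p under 0.05 with these tests. The pericentral call also ended without F1 or F6 (camera adjusted p = 0.0542 and 0.103), the G2 and M phase call without control F5 (0.0570) and the ER stress call without control F5-2 (0.0635). The G2 and M phase median was 0.11, 0.29, 0.31 and 0.44 without F5, F3, F1 and F2, and the phase 1 median -0.05 without F3 or F7. Without F2 the medians of bile duct markers and fatty acid synthesis genes were -0.49 and 0.24, and without F5-2 that of pericentral genes was -0.09. As many as 19 of the 35 divisions of these libraries, the real one included, gave at least 8.

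Library F1 had 23.4% of its counts on the ribosomal RNA gene Rn45s, against 12.5% to 15.01% in the other BKO libraries and 12.8% to 18.1% in the controls. The number of called genes was 17 without F1, 29 without F6, 31 without control F2, 40 without F3 and 51 without control F7, while DESeq2 called 355. Of the 30 named genes besides the targeted ones, 27 lost the call in at least 1 refit, and Cyp3a11, Tcf24 and Slc17a8 kept it in each.

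The third comparison set the change in DKO livers against the change in BKO livers, each over its own controls. It used a single fit of all 16 libraries. Genotype and experiment went together, with separate tables of different depth, so their parts in this difference cannot be told apart. Without a group that lost ARID1A alone, the difference cannot be assigned to the combined loss. H19 differed by 10.62 on the log2 scale (SE 1.07, edgeR adjusted p = 1.79e-05, n = 4 per group), and Ces1f by -8.55 (SE 0.30, edgeR adjusted p = 7.6e-12). The steroid hydroxylase gene Cyp2a4 differed by -6.63 (SE 0.62). Of 23 tested pericentral hepatocyte genes, 1 changed more upward, 16 more downward and 6 did not pass (1 and 17 adjusted over the list alone). Pericentral hepatocyte genes had a median log2 difference of -1.98 (camera adjusted p = 2.91e-22, and adjusted p = 0.000343 with an estimated correlation). Of 35 tested phase 1 enzyme genes, 5 changed more upward, 22 more downward and 8 did not pass (5 and 22 adjusted over the list alone). Phase 1 enzyme genes had a median log2 difference of -1.19 (camera adjusted p = 1.31e-16, and adjusted p = 0.00106 with an estimated correlation). Of 20 tested fetal and oncofetal genes, 12 changed more upward, 0 more downward and 8 did not pass (14 and 0 adjusted over the list alone). Fetal and oncofetal genes had a median log2 difference of 2.61 (camera adjusted p = 9.44e-09, and adjusted p = 0.0009 with an estimated correlation). Of 34 tested matrix genes, 25 changed more upward, 1 more downward and 8 did not pass (28 and 1 adjusted over the list alone). Matrix genes had a median log2 difference of 2.06 (camera adjusted p = 8.48e-29, and adjusted p = 0.00888 with an estimated correlation). Of 18 tested macrophage markers, 12 changed more upward, 0 more downward and 6 did not pass (14 and 0 adjusted over the list alone). Macrophage markers had a median log2 difference of 2.47 (camera adjusted p = 3e-11, and adjusted p = 0.0431 with an estimated correlation). Of 26 tested phase 2 conjugation genes, 3 changed more upward, 10 more downward and 13 did not pass (3 and 14 adjusted over the list alone). Phase 2 conjugation genes had a median log2 difference of -0.58 (camera adjusted p = 7.79e-07, and adjusted p = 0.0147 with an estimated correlation). In all, 1552 genes changed more upward and 1610 more downward in DKO than in BKO livers, of 14050 tested. Arid1a (-0.29, edgeR adjusted p = 0.137) and Arid1b (0.33, edgeR adjusted p = 0.209) did not pass, though Arid1b passed with total-count scaling. That scaling gave 2627 more upward and 744 more downward genes, and moved the median of all genes from -0.01 to 0.27.

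Of 24 tested S phase genes, 1 changed more upward, 0 more downward and 23 did not pass (0 and 0 adjusted over the list alone). S phase genes did not pass as a list (camera adjusted p = 0.309). Log2 fold changes in DKO and in BKO livers, both past the threshold, were higher for Uhrf1 (3.05 and 2.11), Mcm2 (1.65 and 1.53), Mcm4 (1.12 and 1.14), Chaf1a (1.41 and 1.33) and Tcf24 (2.45 and 1.65). They were lower for Ugt3a1 (-4.91 and -2.33), Slc17a8 (-3.92 and -1.67) and the bile salt transporter gene Abcc3 (-2.55 and -0.72). Among 12702 genes tested in both, 17 were called higher in both knockouts and 25 lower in both, where independent lists would share 4.86 and 8.56. The other 34 divisions of the BKO libraries shared 11 to 34 genes with the DKO calls, against 42 for the real groups, when the same number of genes with the smallest p was taken from each, in the direction that shared more. Of the 77 BKO calls tested in DKO livers, 68 (88.3%) had the same sign there, against 55.0% of all genes. Across all genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.17 and Spearman's rho of 0.13. Cyp3a11 did not pass in DKO livers (1324 ± 542 against 1625 ± 327 CPM; log2 fold change -0.30, SE 0.26, edgeR adjusted p = 0.422), and the difference passed (edgeR adjusted p = 8.15e-05). Scnn1a (-2.38 in DKO and 0.70 in BKO) and Sdr9c7 (-4.91 and 1.07) fell in DKO and rose in BKO livers, and Dmxl2 (0.67 and -0.88) did the reverse. These 3 were chosen after their values were seen, and each passed the edgeR test of the difference (adjusted p = 1.22e-05, 2.94e-07 and 1.28e-05).

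**Figure D4:**
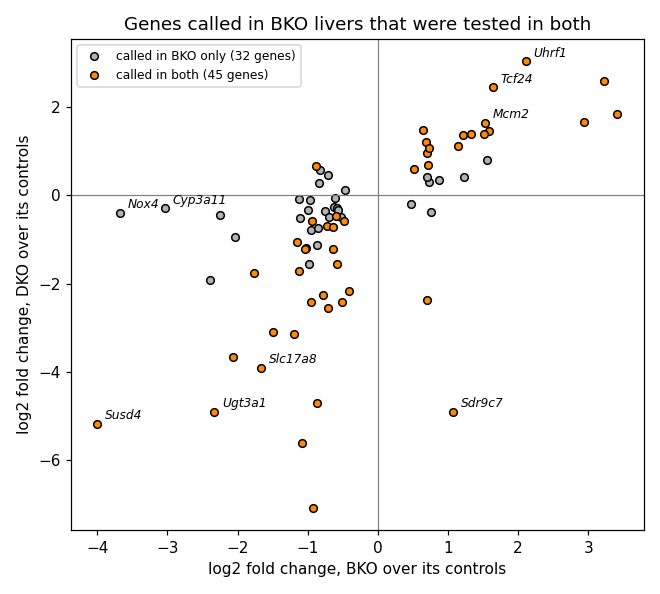
Fitted log2 fold changes of the 77 genes called in BKO livers and tested in both experiments, BKO over its controls on the horizontal axis and DKO over its controls on the vertical axis. Orange points were called in both knockouts (45 genes), grey points in BKO alone (32 genes), and 68 of the 77 had the same sign.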

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

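The tests on cell composition and scaling in DKO livers and on Rn45s in library F1 were chosen after the result was seen, and the scaling test replaced others whose outcome was fixed by their construction. The counts of divisions for lists with an estimated correlation or with fry were added after those for camera at the preset correlation had been seen.

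A single library stood apart in 30 of 380 groups of 4 values examined, gene levels and library measures together. Chance gives about 19 if values are normally distributed, which was not checked. For Wfdc3 in WT-7114 and for Dct and Mup5 in DKO-7112, the other libraries of the group had no count. The rule flags any count in such a group, so these flags carry no information. In library DKO-7112 the albumin share was 3.76%, and normalized CPM stood apart for Igf2bp3 (36.3), Tspan8 (6.62), Ly6d (64.4, others 3.86 to 6.42), Gsta1 (4.34), Tgfb3 (4.02), Dct (0.109) and Mup5 (0.109). In library DKO-7070 they did so for Vim (120.3), H2-Aa (99.6), Cd74 (280.0) and Cyp2a4 (29.7), and in DKO-7137 for Klf6 (106) and Fos (7.25). In control WT-7139 the TMM factor was 0.912, and Dct (9.34), Car3 (2224), Baat (249) and Usp2 (57.5) stood apart. Control WT-7114 did so for Wfdc3 (0.112), Cyp4a12a (15.9), Nr1i3 (198) and Gsta4 (35.4), and control WT-7069 for C1qc (52.9) and Mup21 (1.53). In the BKO experiment these were Uhrf1 in F4 (5.74), Dpy19l3 (5.04) and Fmo2 (91.2) in control F7, Cyp3a11 in control F5 (685) and Rarres1 in control F5-2 (13.3).

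The knockout effects differed between DKO and BKO, by the test of the difference, for 3162 genes (22.5% of those tested) and 29 lists. Of the 148 genes named for DKO that this fit held, 124 passed. Nearly all of these were named for their change in DKO livers, and the same libraries enter the difference. A high share therefore follows from the choice and is no added support. Differences on the log2 scale were -1.86 for Abcc3, -2.62 for Ugt3a1, 11.35 for Tff3, 11.18 for Krt20, 10.83 for Wif1, 10.62 for H19 and 10.08 for Tceal5. They were -12.07 for Sult3a1, -8.55 for Ces1f, -7.35 for Serpina1e, -7.10 for Hamp2 and -6.63 for Cyp2a4. The values of Tff3, Krt20, Wif1, Tceal5 and Sult3a1 were fitted against groups at or near 0 counts and depend on the prior count. The call of Krt20 ended without WT-7069, WT-7139 or F2, without a filter and with limma voom (adjusted p = 0.0530, 0.0555, 1.000, 0.0594 and 0.0618), that of Tff3 without F2 (0.0787) and that of Tceal5 without F7 (1.000). Of the lists called in both knockouts, pericentral genes differed by a median of -1.98 and phase 1 genes by -1.19 (camera adjusted p = 0.000343 and 0.00106 with an estimated correlation). Median differences were 2.62 for bile duct markers, 2.02 for G2 and M phase and -1.83 for fatty acid synthesis genes, calls that were lost with an estimated correlation (adjusted p = 0.131, 0.0574 and 0.131). Bile duct markers were called higher in DKO and lower in BKO livers (medians 0.52 and -0.76), and fatty acid synthesis genes the reverse (-1.63 and 0.42). The bile duct difference covered 20 genes, against 11 tested in DKO livers, so its median is not over the same members. S phase genes, also called in both, had a median difference of 0.12 and did not pass (camera adjusted p = 0.309).

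The 8 libraries of an experiment can be divided into 4 and 4 in 35 ways, the real division included. Only 1 gave as many called genes in DKO livers (4604, highest other 0) and 1 in BKO livers (82, highest other 1). This is the smallest share that 35 divisions can give, and several such counts were made. Chance is thus argued against for both, but not excluded. Mixed divisions hold the knockout effect in their spread, which lowers their calls, and F5 and F5-2 counted as separate animals. Camera list counts were reached by 3 of 35 divisions in DKO (28, highest other 28) and 19 of 35 in BKO (8, highest other 13), so chance cannot be excluded there. With an estimated correlation or with fry, 1 of 35 gave as many lists in DKO (6 and 29, highest other 0 for both), with the same limits. For the difference, 2 of 100 divisions gave as many genes (3162, highest other 3241), 2 as many camera lists (29, highest other 31), 3 as many lists with an estimated correlation (6, highest other 10) and 1 as many with fry (33, highest other 32). Each of these other divisions kept the real DKO grouping and mixed the BKO labels. Chance is therefore argued against, within these limits, for the DKO side of these counts, and not for a difference that rests on the BKO grouping.

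The matrix and macrophage lists rose while the pericentral and phase 1 lists fell in DKO livers. A lower share of hepatocytes would raise all other cell types alike, but the lower quartile of matrix genes lay 1.39 above the upper quartile of endothelial genes on the log2 scale, which argues against it as the whole cause. It would also lower all hepatocyte genes by a single factor. Of 27 plasma protein genes, 25 lay above the pericentral median by more than their error. That error left out the spread of the pericentral genes, and the quartiles of the lists overlapped (-1.22 to 0.04 and -3.04 to -0.63). The comparison therefore speaks only to a loss of all hepatocytes alike. A loss of pericentral hepatocytes in particular was not tested. Of the 80 called members of the matrix, macrophage, pericentral and phase 1 lists, 74 kept call and direction with total counts only. The choice between TMM and total counts therefore does not account for most of these calls. It moved the median of all genes by only 0.18, beside list medians of 2.03, 2.90, -2.20 and -1.24. A larger scaling error could thus not be tested this way. A change in which non-hepatocyte cells were present, and a response within hepatocytes to the loss of ARID1A or of both subunits, may each contribute as hypotheses. They were not told apart in whole liver. An effect of Cre, present in the DKO libraries and not in their controls, cannot be told apart from them.

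Genes called in BKO livers tended to move the same way in DKO livers, which share the loss of Arid1b. Only the real 1 of the 35 divisions of the BKO libraries gave as many shared genes (42, highest other 34). That is the smallest share that 35 divisions can give, so chance is argued against but not excluded. At most 6 of the 40 shared genes with a known place lay on 1 chromosome. This argues against a chromosomal segment carried along with the Alb-Cre transgene as the source of most of them. By the labels the controls carried the same floxed alleles, so a segment beside a floxed allele would be present on both sides. The design thus argues against such a segment. Chromosome 17 held 3: the targeted Arid1b, Chaf1a (56040439 to 56072289) and Uhrf1 (56303321 to 56323486). A segment beside the transgene behind a few genes was not tested. Cre itself was present in both knockouts and in neither control group, and with 0 libraries that had Cre without floxed Arid1b, its effect cannot be told apart from that of Arid1b loss. A shared effect of Arid1b loss therefore stays a hypothesis.

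The number of genes called in BKO livers fell from 82 to 17 without library F1. Whether its high Rn45s share plays a part cannot be told apart: 98.8% of the calls (81) remained when the 20 most abundant genes, Rn45s among them, were removed, but this removal kept F1 and so did not test the fall. Fold changes that rest on F1 are argued against, since the median ratio of the log2 fold changes without F1 to those with it was 0.987. Standard errors grew by a median of 1.11 times without F1, but also by 1.12 times without F3 and 1.09 times without F4, where 40 and 104 genes were called, so what sets F1 apart stays open. No biological explanation was tested for this pattern.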

How the results depend on the processing

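The refits on DKO-7068 and DKO-7070 summed and on F1 and F5-2 both left out, and those of the lists with DESeq2 size factors or without the 20 most abundant genes, and the levels of named genes with a library left out, were chosen after the data had been seen. In DKO livers, 3840 to 4584 genes were called with each library left out in turn, 5350 with all 16 libraries in one fit, 5232 with the tag series as a batch and 3965 with DKO-7068 and DKO-7070 summed. Of 2626 refits of the 146 named genes, 2611 kept direction and side of the threshold, 15 lost the call and none reversed. A 2-fold minimum left 2136 genes (1433 higher, 703 lower), by its construction. Total counts only gave 1269 lower genes, 72.0% of calls higher against 53.6%. The Arid1b change was -0.39 with total counts only, and -0.75 to -0.46 with a library left out, passing in each except without DKO-7068. With an estimated correlation 6 lists were called in place of 28, and with fry 29, of which 25 were among the 28. In BKO livers, a 2-fold minimum left 38 genes (14 higher, 24 lower). Total counts only gave 86 lower genes and 20.4% of calls higher, against 31.7%. The DESeq2 Wald test gave 355 (152 higher, 203 lower; 42.8% higher), and limma voom 17 higher. With a library left out, the called genes ran from 17 to 104, the higher from 4 to 33 and the lower from 13 to 73. The call count was 17 without F1, 40 without F3, 29 without F6, 31 without F2 and 51 without F7, and the lower count 37 without F5. All 16 libraries in one fit gave 50 (13 higher, 37 lower). With both F5 libraries summed, 104 genes were called (38 higher, 66 lower), 67 of the 82 among them. Leaving out F1 and F5-2 gave 43 (17 higher, 26 lower) and 13 lists. Of 538 refits of the 30 named genes, 383 kept the call, 155 lost it and none reversed. Arid1a, not called, reversed to -0.0095 with total counts only. An estimated correlation left 0 lists and fry 0, of 8. For the difference, a 2-fold minimum left 1782 genes, 660 of them more downward, and total counts only gave 2627 more upward and 744 more downward (77.9% upward against 49.1%). An estimated correlation left 6 of 29 lists, and 2618 to 3314 genes were called with a library left out. The Tff3 difference did not pass without F2, that of Tceal5 without F7, and that of Krt20 without WT-7069, WT-7139 or F2, without a filter or with limma voom, while Arid1b passed with total counts only. Genes shared between the knockouts in the same direction were 143 with DESeq2 in place of 42. The cause of these changes was not tested, except where fewer libraries or a size minimum set them by construction. At the depth of the DKO experiment, edgeR recovered 10.4% of 1.5-fold changes in a simulation with 200 changed genes. With 4604 genes called, the adjusted threshold in DKO livers was less strict than there.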

Other observations

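Of 22 tested female-biased liver genes, 0 rose, 16 fell and 6 did not pass (0 and 16 adjusted over the list alone). Female-biased liver genes had a median log2 fold change of -2.24 (camera adjusted p = 6.85e-11, and adjusted p = 0.0669 with an estimated correlation). Cyp2a4 was at 12.6 ± 11.4 against 1000.3 ± 254 CPM, with a DKO mean of 6.93 CPM without DKO-7070. Of 12 tested male-biased liver genes, 1 rose, 8 fell and 3 did not pass (1 and 8 adjusted over the list alone). Male-biased liver genes had a median log2 fold change of -2.29 (camera adjusted p = 5.24e-05, and adjusted p = 0.137 with an estimated correlation). The organic anion transporter gene Slco1a1 was at 12.9 ± 4.62 against 276 ± 90.6 CPM. In the same DKO libraries the albumin share was lower (3.76% to 6.38% against 8.62% to 9.94%) and recruited macrophage markers were higher (median 2.90). Of 22 tested liver transcription factor genes, 2 rose, 7 fell and 13 did not pass (2 and 7 adjusted over the list alone). Liver transcription factor genes did not pass as a list (camera adjusted p = 0.0781). Nr1h4, which encodes the bile acid receptor FXR, fell 2.59-fold and Nr1i3, which encodes the xenobiotic receptor CAR, 3.24-fold. Of 26 tested BAF and PBAF subunit genes, 1 rose, 4 fell and 21 did not pass (0 and 4 adjusted over the list alone). BAF and PBAF subunit genes did not pass as a list (camera adjusted p = 0.182). Those that fell included the targeted Arid1b itself, and Smarcd2, whose call ended with total-count scaling (edgeR adjusted p = 0.150). The ATPase gene Smarca2 fell 2.52-fold (99.7 ± 17.2 against 251 ± 24.0 CPM; log2 fold change -1.33, SE 0.15, edgeR adjusted p = 0.000103). Lipoprotein lipase (Lpl), which releases fatty acids from lipoproteins, rose 17.9-fold (296 ± 31.2 against 16.6 ± 6.21 CPM).

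Of 14 tested immediate early genes, 10 rose, 0 fell and 4 did not pass (11 and 1 adjusted over the list alone). Immediate early genes had a median log2 fold change of 2.07 (camera adjusted p = 5.91e-05, and adjusted p = 0.137 with an estimated correlation). Klf6 rose 4.67-fold and Jun 2.57-fold. Of 19 tested clock genes, 0 rose, 7 fell and 12 did not pass (1 and 8 adjusted over the list alone). Clock genes had a median log2 fold change of -0.57 (camera adjusted p = 0.00871, and adjusted p = 0.173 with an estimated correlation). Per1 fell 1.55-fold and Hlf 2.91-fold. Recruited macrophage markers (median 2.90) and matrix genes (median 2.03) rose in the same DKO libraries. Of 19 tested glycolysis and hypoxia genes, 4 rose, 6 fell and 9 did not pass (5 and 6 adjusted over the list alone). Glycolysis and hypoxia genes did not pass as a list (camera adjusted p = 0.345). The glycolytic gene Pkm rose 3.03-fold and Pdk1, which restrains pyruvate oxidation, fell 6.65-fold. Neutrophil markers could be tested only in the difference of the knockout effects, since fewer than 5 passed the count filter in either separate fit. Of 8 tested neutrophil markers, 6 changed more upward, 0 more downward and 2 did not pass (7 and 0 adjusted over the list alone). Neutrophil markers had a median log2 difference of 4.61 (camera adjusted p = 0.000731, and adjusted p = 0.177 with an estimated correlation). Fitted differences of members at or near 0 counts in a group depend on the prior count, so the size of this median is uncertain. Of 33 tested ribosomal protein genes, 2 rose, 0 fell and 31 did not pass (0 and 0 adjusted over the list alone). Ribosomal protein genes did not pass as a list (camera adjusted p = 0.723). Among the other lists that did not pass in DKO livers, 4 of 25 cholesterol synthesis genes and 6 of 13 bile transport genes fell, and 2 of the latter rose (camera adjusted p = 0.0808 and 0.07). In ER stress genes 5 of 23 rose and 1 fell, and in lipid droplet genes 4 of 16 rose and 4 fell (camera adjusted p = 0.267 and 0.825). Of B and plasma cell markers 3 of 5 rose, and of pancreas and fat markers 1 of 10 fell (camera adjusted p = 0.295 and 0.601).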
